A study of Mus musculus with 26 samples.

How the data were processed

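RNA was sequenced from tongue tissue of male CBA mice, an inbred strain, in a model of oral carcinogenesis that uses 4-NQO, a compound that damages DNA. Per the labels' protocols, thin sections of paraffin-embedded tongue were stained with cresyl violet, and regions were cut out by laser where a pathologist had mapped them, as epithelium or as the stroma and muscle beneath it. Each library was labelled with its compartment, its histology (normal, hyperplasia, dysplasia or tumor), the age of the mouse in weeks and 1 of 2 sequencing runs. The labels call the libraries of a group biological replicates but do not state the animal, so p-values may measure the spread between samples or regions that share an animal and would then be too small. The human leukoplakia samples and the immunostaining of this study were not analysed here.

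The deposited table held log2 values of TPM, a length-scaled relative abundance, plus a pseudocount of 1, as made by the authors, from 0 to 18.67. Per the submitters' processing notes, the tools were bcl2fastq 2.20, FastQC 0.11.5, Trimmomatic 0.36, STAR 2.5.1b, SAMtools 1.6, HTSeq 0.10.0 and Salmon 0.9.1, with the mouse genome build GRCm38.p6. The notes give no role or order for these tools. The scale and pseudocount were read from the values, since taking them back to TPM gave library totals of at most 895312, within what TPM can sum to. TPM keeps no record of sequencing depth, so the depth behind each value is unknown and no counting interval was computed. A log2 difference on this scale understates the change of genes with low values.

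The table had 18676 rows, each pairing a mouse gene with a human ortholog, for 17023 mouse gene identifiers. For 626 identifiers the gene stood in several rows (2279 in all), whose values could not be assigned to a single gene, so the 16397 rows with an identifier of their own were used. That choice was made after the table was seen, and the analysis with all rows is among the alternatives. It leaves out close paralogs such as Krt6a, H2-K1 and the amylases. Of the identifiers, 17011 were found in a table of gene names and 16868 carried the same symbol there. Coordinates came from an annotation of GRCm38, the build the notes name, and were taken by gene identifier. The table held 0 columns of samples outside the 26 libraries.

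Tests were run in R 4.3.3 with limma 3.58.1. Within each compartment a linear model with the 4 stages and the sequencing run as terms was fitted to genes with a TPM of at least 1 in at least 3 libraries of that fit, with empirical Bayes moderation that follows the mean level. This left 14126 genes in epithelium and 14883 in stroma, with 8 residual degrees of freedom and prior degrees of freedom of 13.5 and 71.8. SEs and p-values, most of all in stroma, therefore rest largely on a spread pooled over genes of similar level. They can be too small for a gene whose own libraries differ widely. Hyperplasia was compared with normal, dysplasia with hyperplasia, tumor with dysplasia, and tumor with normal, and an F test asked whether a gene differed among the stages at all. Epithelium was compared with stroma in the differences within 13 pairs (15499 genes, prior degrees of freedom 15.5), averaged with equal weight over the 4 stages, and the same differences tested whether the tumor change differed between compartments. Pairs were formed from the number in the sample code, age and run, which matched for each epithelium library with a single stroma library of its stage. A letter B that follows some numbers was not used. It stands in the code of only a single partner for normal epithelium 1, hyperplasia epithelium 1 and dysplasia epithelium 2 and 3. Deviations of those partners correlated at 0.08, -0.07, 0.08 and 0.35. The labels do not state these pairs, and in 4 of the 13 the replicate numbers of the titles differ. Partners' deviations from their group means correlated between -0.12 and 0.60, and 7 of 13 pairs were over 0.1. Among only the 3 or 4 stroma libraries of their stage, 8 of 13 epithelium libraries were closest to their partner. With so few candidates several would be closest by chance, and partners also share a run, so this does not establish the pairs. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05.

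The comparisons, the tests, the rule for naming genes and 38 gene lists were fixed before the data were examined. The lists hold 598 entries, of which 505 were in the rows used, and 37 lists with at least 3 kept genes were tested in each comparison. Lists were tested with limma's fry, which asks whether a list's genes move on balance in a single direction and does not compare them with other genes, with adjustment over the lists. Camera with an estimated correlation between genes, which does compare a list with the other genes, was run as the alternative. A list score is the mean log2 value of a list's kept genes in a library. Named genes were, per comparison, up to 10 in each direction with the largest moderated t among those that passed with a log2 change of at least 1, leaving out predicted and clone names. Where none passed, up to 3 with the smallest p were given as values. From each list described, up to 4 members that passed, or else up to 2 with the highest level, were added, as were the genes of the immunostained markers. Genes named outside that rule are marked as chosen after their values were seen. Some genes that the rule would name are not reported here.

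The fits were tested on simulated data made from the real values, with 10 draws per comparison. Of genes given a log2 change of 1, 2 and 3, the tumor against normal test recovered 3.13%, 32.2% and 80.5% in epithelium, with 123 calls among unchanged genes over all draws. In stroma it recovered 0%, 0% and 4.09%, with 2 such calls. The comparison of epithelium with stroma recovered 0%, 98.1% and 100%, with 0 such calls. Only genes with a mean log2 value over 3 were given these changes, so the shares do not hold for lower genes. The spread of the compartments was shuffled separately, so simulated partners were unrelated, unlike some of the real pairs. A list moved by a log2 of 2 was called in 6 of 10 draws in epithelium and 0 of 10 in stroma, and 0 of 360 tests of the other lists were called in either.

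Alternatives fixed in advance were a pseudocount of 0.1, no filter, a filter at a TPM of 5, no run term, quantile normalization, limma's library weights, age as a covariate, the replicate number of the titles as a block, the muscle list score as a covariate in stroma, no pairing, camera, and leaving out each library or pair in turn. Limma's default estimate of library weights stopped without converging in all 3 fits, with weights from 1.82e-13 to 175 in stroma, so its counts carry little weight. Its gene-by-gene estimate gave no warning, with stroma weights from 0.0859 to 8.62, and was added after the data were seen. Also added then were all rows, median centring, TPM rescaled without Lars2, March6 and D17H6S53E, and leaving out hyperplasia stroma 1 and dysplasia stroma 2 together.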

Results

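The data were 26 RNA-seq libraries of laser-dissected tongue, 13 of epithelium and 13 of stroma. Normal, hyperplasia and tumor had 3 libraries each per compartment and dysplasia had 4, with both sequencing runs in every group. A run held only 1 or 2 libraries of a group. Tests within a run would have been weak and were not made, and run was a term in each fit. Mice were 16 to 24 weeks old for normal tissue, 20 to 32 for hyperplasia, 16 to 32 for dysplasia and 28 to 32 for tumor. Age ranges overlapped in part between stages but not between normal and tumor, so a difference between those 2 may also follow age. The labels do not say whether the mice that gave normal tissue received 4-NQO, so a difference from normal tissue cannot be assigned to lesion or treatment. The study set out to define the genes that change at each step of transformation in both compartments and to follow the immune infiltrate. Values are log2(TPM + 1), given as mean ± SD, and changes are log2 differences ± SE from limma.

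The libraries differed in how their transcripts were spread over genes. The 3 genes Lars2, March6 and D17H6S53E held a median of 1.03% of the TPM per library but 87.0% in hyperplasia stroma 1, 55.0% in dysplasia stroma 2, 48.4% in normal stroma 1 and 18.2% in dysplasia epithelium 2. In hyperplasia stroma 1, 9382 genes were listed at 0 and 4681 had a TPM of at least 1, against up to 15519 in the other libraries. Olfactory receptor genes, which tongue tissue is not known to use widely and which here stand for background, had a mean log2 value from 0.40 in hyperplasia stroma 1 to 2.36 in hyperplasia stroma 2, where 92.3% of the 156 genes reached a TPM of 1. The rows of the table summed to between 179645 and 895312 TPM per library. No libraries were identical, and the highest Spearman correlation across genes was 0.98, between dysplasia epithelium 1 and 4.

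**Figure D1:**
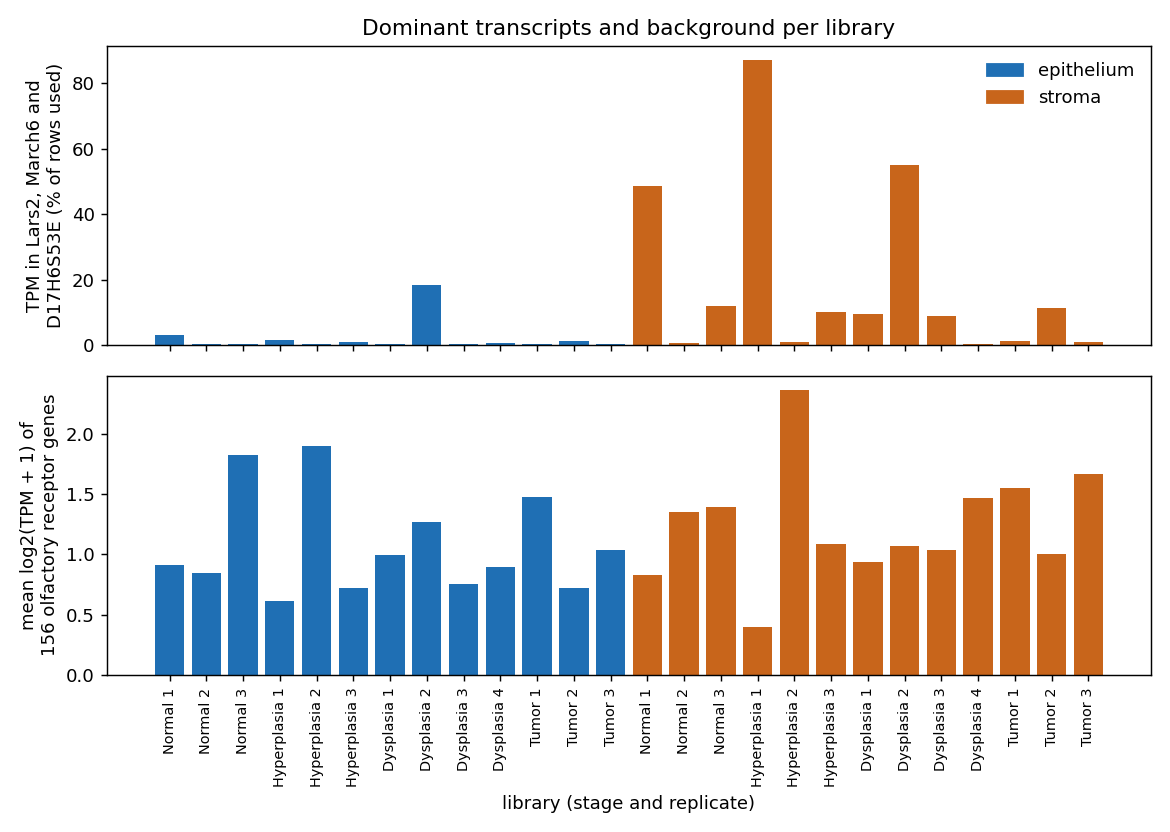
Bars give, for each of the 26 libraries, the percent of TPM in Lars2, March6 and D17H6S53E (upper panel) and the mean log2(TPM + 1) of 156 olfactory receptor genes (lower panel), epithelium in blue and stroma in orange. Hyperplasia stroma 1 stands at 87.0% and dysplasia stroma 2 at 55.0%, and the background is highest in hyperplasia stroma 2 at 2.36.

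The comparison of epithelium with stroma asked how far the dissection separated the compartments. Genes of the cornified layers were far higher in epithelium, among them Gjb2, a gap junction protein (5.02 ± 0.34, adjusted p = 3.11e-09), Krt16, a keratin of stressed epithelium (4.97 ± 0.35), Dsc1, a desmosomal cadherin (5.34 ± 0.41), and the crosslinking enzymes Tgm1 (4.02 ± 0.32) and Tgm3 (4.39 ± 0.36). Genes of the connective tissue were higher in stroma, among them the collagens Col3a1 (-3.65 ± 0.28, adjusted p = 9.1e-09), Col1a2 (-3.42 ± 0.27) and Col1a1 (-3.14 ± 0.27), the matrix proteins Bgn (-3.41) and Mfap4 (-4.02), and the chemokine Cxcl12 (-3.05). Each of these genes differed in the same direction in 13 of 13 pairs. In all, 2994 genes were higher in epithelium and 1683 in stroma of 15499 tested, of which 2022 and 1110 differed at least 2-fold. Further leading genes were Lypd3, Defb14, Krt84, Elovl4 and Il1f6 in epithelium (3.90 to 5.12) and Rarres2, Ccdc80, Wisp2 and Aqp1 in stroma (-3.63 to -3.06). The split of 2994 against 1683 moved to 2821 against 2683 under quantile normalization, 3062 against 2554 under median centring, and 2879 against 2683 without hyperplasia stroma 1 and dysplasia stroma 2. It was 1603 against 2625 after rescaling without the 3 dominant genes, which moved the median over genes from 0.16 to -0.15.

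Of the keratinocyte lists, all 19 members of oral keratinocyte differentiation were higher in epithelium (median 4.28, limma fry adjusted p = 0.000136), with Rptn at 5.69. So were 7 of 7 members of stress keratin and wound response (median 3.07, adjusted p = 0.000136 by limma's fry). For filiform papilla and hard keratin, the keratins of the tongue's papillae, 7 of 8 were higher (median 2.32, limma fry adjusted p = 0.000249). Camera with an estimated correlation gave an adjusted p = 0.127 for each of these 3 lists. The basal keratinocyte list did not pass, with 6 members higher and 1 lower of 12 (median 0.94, adjusted p = 0.113), among them Trp63, the regulator of basal cells (1.64), and Krt5 (1.62). Antioxidant targets of NRF2 were higher in epithelium in 8 of 12 members, such as Hmox1 (2.80) and Nqo1 (1.81), with adjusted p = 0.00111. Hypoxia and glycolysis genes were higher in 9 of 15, such as Egln3 (2.46), with adjusted p = 0.0020, and ribosomal protein genes in 10 of 10 (median 1.25, adjusted p = 0.00777). Among p53 targets 8 of 18 were higher, such as Perp (3.35) and Cdkn1a (1.96), with adjusted p = 0.0104. The immediate early and heat shock list had 5 members higher and 1 lower of 10 (adjusted p = 0.00777). The list of genes often altered in oral carcinoma had 7 higher, such as Hras (2.08) and Erbb2 (1.86), and 1 lower of 17 (adjusted p = 0.0244). With an estimated correlation these 6 lists had an adjusted p of 0.308, 0.390, 0.458, 0.586, 0.587 and 0.609. The carcinoma list was lost without the pair of normal epithelium 2 (0.0714), normal epithelium 3 (0.0539), dysplasia epithelium 4 (0.0527), tumor epithelium 1 (0.0558) or tumor epithelium 3 (0.0563).

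Lists of connective tissue, vessels, muscle and nerve were higher in stroma. Members lower in epithelium numbered 21 of 22 for matrix and activated fibroblast (median -2.03, limma fry adjusted p = 0.000249). They numbered 10 of 11 for resting fibroblast (median -2.29, such as Dpt at -3.46 and Lum at -3.23, adjusted p = 0.000523), 14 of 15 for endothelium (median -1.71, such as Plvap at -2.47, adjusted p = 0.00126) and 21 of 23 for skeletal muscle (median -2.92, such as Acta1 at -3.75, adjusted p = 0.0020). The same held for 8 of 10 in the epithelial-mesenchymal transition list (Vim -2.88, Zeb1 -2.40, adjusted p = 0.00111) and 7 of 10 in the Schwann cell list (adjusted p = 0.00111). It held for 4 of 7 in the mast cell list (Cpa3 -1.82, adjusted p = 0.000487) and 2 of 10 in the adipocyte list (adjusted p = 0.0235). With an estimated correlation the adjusted p of these 8 lists was 0.127 for the fibroblast and mast cell lists, 0.169 for endothelium and Schwann cell, 0.171 for muscle, 0.234 for transition and 0.307 for adipocyte. The adipocyte list was lost without the pair of normal epithelium 2 (0.0714), hyperplasia epithelium 2 (0.0723), hyperplasia epithelium 3 (0.0513), tumor epithelium 2 (0.0571) or tumor epithelium 3 (0.0562).

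Macrophage genes were higher in stroma, with 11 members of the macrophage and monocyte list lower in epithelium and 1 higher of 17 (median -1.09, limma fry adjusted p = 0.0163, 0.320 with an estimated correlation). C1qa, a complement gene of tissue macrophages, was at -2.36. The M2 macrophage list had 6 members lower, such as Lyve1 (-2.63) and Mrc1 (-2.09), and 3 higher of 13, and its fry test gave an adjusted p of 0.0435, and 0.464 with an estimated correlation. Arg1, the arginase, was higher in epithelium by 4.11 ± 0.47. The M2 list was lost without any of 11 of the 13 pairs, with an adjusted p from 0.0559 without that of hyperplasia epithelium 3 to 0.113 without that of hyperplasia epithelium 2. It held only without the pair of hyperplasia epithelium 1 or tumor epithelium 1. Of the immunostained markers, Ptprc (CD45, whose B220 form marks B cells, -1.33 ± 0.30), Adgre1 (F4/80, -1.28 ± 0.28) and Cd163 (-1.87 ± 0.29) were lower in epithelium (adjusted p = 0.00155, 0.0013 and 3.06e-05). Their list passed (adjusted p = 0.00819, 0.308 with an estimated correlation). Cd3e (-0.25), Cd4 (-0.27), Cd8a (-0.32), Foxp3 (-0.03) and Nos2 (-0.30) did not pass.

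**Figure D2:**
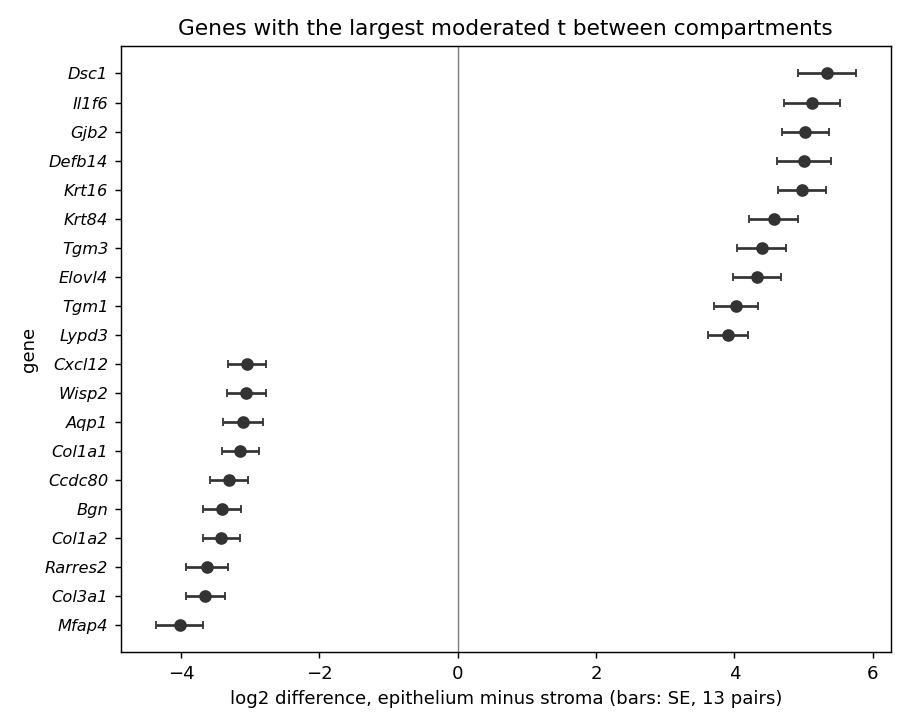
Points give the log2 difference of epithelium minus stroma averaged over the 4 stages, with bars for the SE over 13 pairs, for the 10 genes with the largest moderated t in each direction. Keratinocyte genes lie between 3.90 and 5.34 and connective tissue genes between -4.02 and -3.05.

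In epithelium, 5 genes changed from normal mucosa to hyperplasia, 2 of them of the MHC class I pathway, which displays peptides to cytotoxic T cells. B2m, the light chain of class I molecules (chromosome 2, 122147686 to 122153083), was at 9.24 ± 1.25 in hyperplasia and 4.19 ± 0.04 in normal epithelium, a rise of 5.17 ± 0.69 (n = 3 and 3, adjusted p = 0.00254). Nlrc5, the transactivator of class I genes (chromosome 8, 94434356 to 94527272), rose by 3.73 ± 0.61 (5.14 ± 1.14 against 1.46 ± 0.54, adjusted p = 0.0172). Gprc5d (-2.69 ± 0.42, adjusted p = 0.0140), the homeobox gene Tlx1 (-4.39 ± 0.76) and Kif26a (-2.29 ± 0.40, both adjusted p = 0.0312) fell. All 3 hyperplasia libraries lay beyond the normal range for each of the 5 genes. These 2 genes up and 3 down were all that passed of 14126, with 518 genes at an unadjusted p under 0.05. Without normal epithelium 1 or hyperplasia epithelium 1 the count was 0, with B2m at 5.10 (adjusted p = 0.0750) and 4.66 (adjusted p = 0.165). Without normal epithelium 2 it was 1, and without hyperplasia epithelium 2 or 3 it was 29 and 30. Nlrc5 and Tlx1 were also lost without normal epithelium 2 (adjusted p = 0.138 and 0.155), and Kif26a without normal epithelium 2 or 3 (0.268 and 0.0584). Tlx1 and Kif26a each held in 9 of 18 alternatives, with losses under no filter (0.0794 and 0.0542) and a pseudocount of 0.1 (0.0776 each) as well.

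All 12 measured genes of the antigen presentation list had positive values in hyperplasia against normal epithelium (median 2.62), 2 past the test over all genes and 11 when adjusted over the list alone. Its fry test gave an adjusted p of 0.0544. The list passed under quantile normalization (0.00266), rescaling (0.00533), median centring (0.00829), gene-by-gene weights (0.0122), no run term (0.0368), a pseudocount of 0.1 (0.0429) and the stricter filter (0.0431), and without hyperplasia epithelium 2 (0.0203). It did not pass with camera (0.0675), no filter, all rows, age as a covariate or any other library left out. The immunoproteasome genes Psmb8 (3.11, adjusted p = 0.0736) and Psmb9 (2.83, adjusted p = 0.0689) and the peptide transporter Tap1 (2.59, adjusted p = 0.10) were given by value after they were seen. All 15 genes of the type I interferon list had positive values (median 1.46, 0 past the test and 12 adjusted over the list alone). Its limma fry adjusted p was 0.119, and 0.0468 without normal epithelium 3, 0.0308 under quantile normalization and 0.0122 with gene-by-gene weights. Default weights, which did not converge, gave 0.00273, and no other alternative passed. Stress keratin genes had a median of 2.42 (5 of 7 adjusted over the list alone, adjusted p = 0.218), with Krt16 at 10.85 ± 0.65 against 8.42 ± 0.79. Macrophage genes had a median of 1.19 (8 of 16 adjusted over the list alone, adjusted p = 0.231). Under quantile normalization the stress keratin and macrophage lists had a fry adjusted p of 0.0254 and 0.0247. With gene-by-gene weights stress keratin had 0.0122. Default weights aside, neither list passed under another alternative. Of 37 lists 0 passed with fry or with camera, and 7 had an unadjusted fry p under 0.05.

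From hyperplasia to dysplasia, epithelium had no gene past limma's test, with 0 up and 0 down and 279 genes at an unadjusted p under 0.05. Library weights estimated by limma's default and gene by gene gave 2963 and 256 genes. The smallest p-values belonged to Gpnmb (3.00 ± 0.69), Mal (2.32) and Grem1, a BMP antagonist (1.66), in the positive direction, and Cr2 (-2.10), Pla2g5 (-1.82) and Ccdc40 (-1.46) in the negative. All 19 differentiation genes had negative values (median -0.95, 0 past the test over all genes or adjusted over the list alone, limma fry adjusted p = 0.985). B2m stood at 8.61 ± 0.79 in dysplasia (-0.69 ± 0.63). Without dysplasia epithelium 2 the count was 5, and without dysplasia epithelium 1 it was 1.

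From dysplasia to tumor, 0 genes passed in epithelium, with 322 at an unadjusted p under 0.05 and a smallest adjusted p of 0.260. With library weights by default and gene by gene 1857 and 1423 passed. Those with the smallest p were Myl4 (2.61 ± 0.49), the heat shock protein Hspb7 (2.5) and the fibril-associated collagen Col12a1 (2.28) in the positive direction, and Cpxm2 (-1.92), the homeobox gene Irx2 (-1.85) and the serotonin transporter Slc6a4 (-1.6) in the negative. All 22 matrix and activated fibroblast genes had positive values (median 1.18, 0 past the test and 11 adjusted over the list alone), with a limma fry adjusted p of 0.295 and 0.0135 without tumor epithelium 1. All 22 skeletal muscle genes did too (median 2.39, 18 adjusted over the list alone, adjusted p = 0.465), and the muscle score was 3.97 ± 0.98 in tumor and 1.61 ± 0.31 in dysplasia epithelium. Without dysplasia epithelium 2 the count was 8 and without tumor epithelium 1 it was 2.

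Against normal epithelium, tumor epithelium had B2m (4.04 ± 0.69, adjusted p = 0.0322) and Nlrc5 (3.31 ± 0.61, adjusted p = 0.0442) higher. Col12a1 (chromosome 9, 79598991 to 79718831) rose by 3.27 ± 0.52 (4.92 ± 1.28 against 1.75 ± 0.32, n = 3 and 3, adjusted p = 0.0284). So did Pthlh, the parathyroid hormone-like protein (3.58 ± 0.64), the actin-bundling protein Fscn1 (3.47 ± 0.64, both adjusted p = 0.0442) and the glycosyltransferase Galnt6 (2.73 ± 0.51, adjusted p = 0.0484). The protease inhibitor Spink6 fell by 3.25 ± 0.53 (0.67 against 3.75, adjusted p = 0.0284). These were 6 up and 1 down of 14126, with 629 at an unadjusted p under 0.05. The count was 0 without normal epithelium 1, normal epithelium 2 or tumor epithelium 2, 1 without tumor epithelium 3 and 25 without tumor epithelium 1, and it was 3, with 0 up, when age was a covariate. Without normal epithelium 3, B2m, Pthlh, Fscn1 and Galnt6 had an adjusted p of 0.0592, 0.0565, 0.0534 and 0.120. Of 18 alternatives, Pthlh held in 6, Fscn1 in 9, Galnt6 in 10, B2m and Nlrc5 in 11, and Col12a1 and Spink6 in 12. Col12a1 belongs to the matrix and activated fibroblast list, which was higher in stroma than in epithelium. Muscle genes, also higher in stroma, had positive values in tumor against dysplasia epithelium. Whether the rise of Col12a1 lay in the epithelium or in stroma dissected with it was not tested.

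B2m and Nlrc5 were the 2 genes called up in both hyperplasia and tumor epithelium. Unchanged groups simulated against the same normal libraries shared 0.02 genes on average and at most 1 over 100 draws, and independent lists of these sizes would share 8.49e-04. With 3 normal libraries the controls could not be split, so part of the excess may come from the shared controls. Lists in tumor against normal epithelium had positive medians without passing fry. Stress keratin had 7 of 7 positive (median 2.66, 0 past the test, 5 adjusted over the list alone), matrix 20 of 22 (median 1.47, 1 past the test, 14 adjusted over the list alone), macrophage 15 of 16 (median 1.61, 0 and 12) and inflammatory cytokines 14 of 15 (median 0.98, 0 and 6), each with adjusted p = 0.122. Without tumor epithelium 1 the matrix list had 0.0122 and the inflammatory list 0.0283. Antigen presentation had 12 of 12 positive (median 1.71, 2 and 9, adjusted p = 0.127) and cell cycle 28 of 28 (median 0.89, 0 and 0, adjusted p = 0.222), with matrix protease and M2 macrophage at medians of 1.01 and 0.54 (adjusted p = 0.222 each). Each of these lists passed fry under quantile normalization (adjusted p from 6.28e-04 for M2 macrophage to 0.0323 for cell cycle). With median centring, stress keratin, matrix, inflammatory and antigen presentation had 0.0317 and macrophage 0.0475. With rescaling, stress keratin had 0.0202 and antigen presentation 0.0224. None passed with camera, a pseudocount of 0.1, no filter, the stricter filter or no run term.

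**Figure D3:**
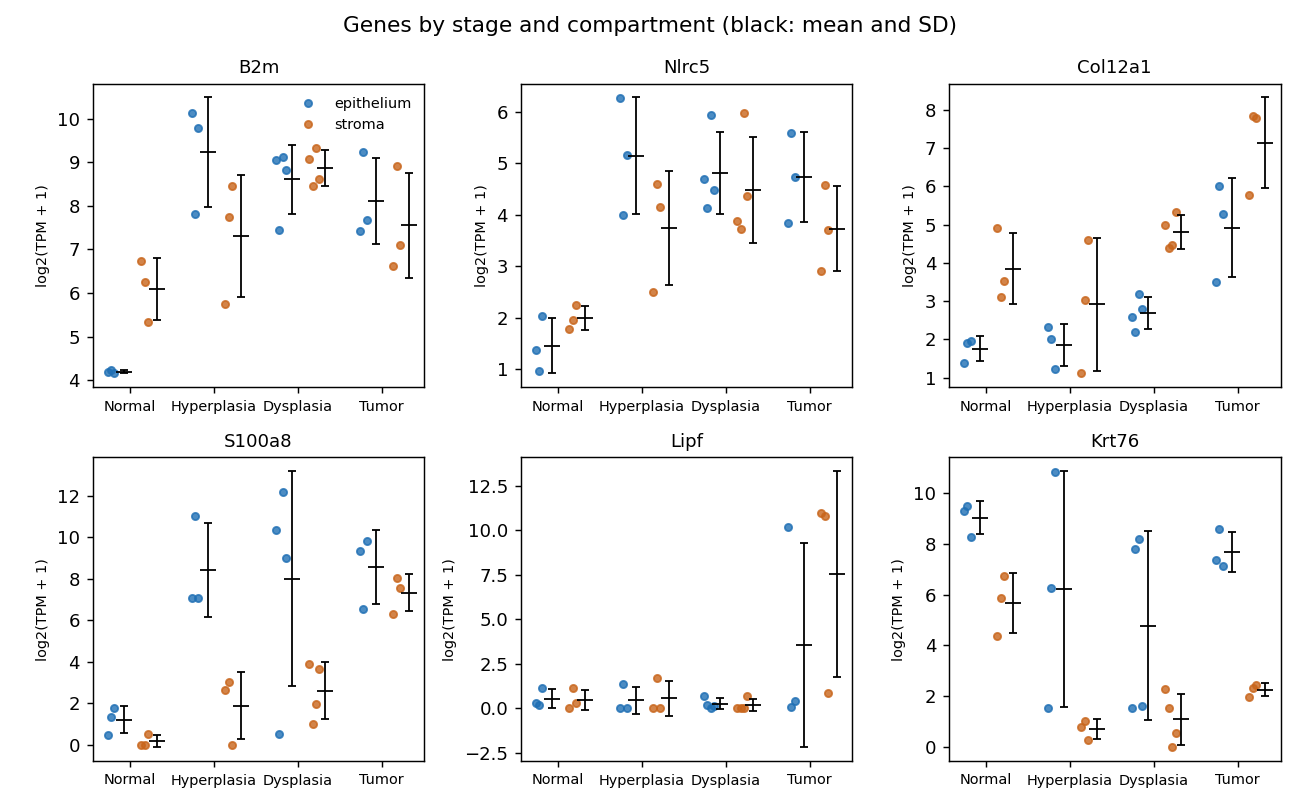
Each panel gives log2(TPM + 1) of a gene by stage, with a point per library (epithelium blue, stroma orange) and the mean and SD in black. B2m in epithelium lies near 4.19 in normal tissue and at 9.24, 8.61 and 8.11 at later stages, and Lipf is high in tumor in only part of the libraries.

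In stroma, the step to hyperplasia changed a single gene past the threshold. Krt76, a keratin of differentiated oral epithelium (chromosome 15, 101884351 to 101892920), fell by 4.78 ± 0.92 (0.70 ± 0.39 against 5.66 ± 1.18, n = 3 and 3, adjusted p = 0.0232), and 1029 genes had an unadjusted p under 0.05. The median over all genes was -0.72, and it was 0.16 without hyperplasia stroma 1, 0.38 with median centring and 0.06 with quantile normalization. All 18 differentiation genes had negative values (median -3.41, 1 past the test, 16 adjusted over the list alone, limma fry adjusted p = 0.263). So had all 7 filiform papilla genes (median -2.31, 0 past the test, 4 adjusted over the list alone), with a limma fry adjusted p of 0.0716, and 0.0126 without normal stroma 1. The differentiation list, which holds Krt76, and the filiform papilla list were both higher in epithelium than in stroma. Whether these lower values lay in stroma or in epithelium dissected with it was not tested. Skeletal muscle had a median of -2.78 (19 of 23 adjusted over the list alone, adjusted p = 0.310), nuclear oxidative phosphorylation genes -2.24 (adjusted p = 0.326), mitochondrially encoded genes -1.50 (adjusted p = 0.310) and Schwann cell genes -1.26 (adjusted p = 0.269). Smallest in p in the positive direction were Slc1a2, a glutamate transporter (3.44), Ccdc24 (2.96) and Pate3 (2.45). The count was 0 without normal stroma 2 or 3 or hyperplasia stroma 1 or 2, 23 without normal stroma 1 and 94 without hyperplasia stroma 3, and 108 with age as a covariate. Krt76 was lost at 4 of these libraries, with an adjusted p from 0.157 without hyperplasia stroma 2 to 0.624 without hyperplasia stroma 1. It held in 9 of 20 alternatives, and its highest adjusted p was 1.00 with the muscle score as a covariate (-4.54).

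From hyperplasia to dysplasia, stroma had 0 genes up and 0 down with limma, 1139 at an unadjusted p under 0.05 and a smallest adjusted p of 0.277. Library weights by default and gene by gene gave 1663 and 0. The median over all genes was 0.65. Genes with the smallest p were Rgs10 (4.35), Samd12 (3.90) and Sh3bp2 (3.29) in the positive direction and Slc1a2 (-3.56), Arhgef39 (-3.32) and Ccdc24 (-3.18) in the negative. All 17 macrophage genes (median 1.43), 12 of 12 M2 genes (1.30), 13 of 13 dendritic cell genes (1.28) and 12 of 12 antigen presentation genes (1.78) had positive values, each with a limma fry adjusted p = 0.478 and 0 past the test. With median centring C1qa, for example, went from 0.88 to -0.14. Adgre1 was at 3.76 ± 1.30 in dysplasia and 1.61 ± 1.44 in hyperplasia stroma (2.24 ± 0.88, adjusted p = 0.637), and Cd163 at 3.70 ± 0.93 and 1.77 ± 1.59 (2.00 ± 0.88, adjusted p = 0.637). Without hyperplasia stroma 3 the count was 38, without dysplasia stroma 1 it was 3 and without dysplasia stroma 4 it was 2.

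From dysplasia to tumor, the stress keratin and wound response list and single genes of salivary gland secretion rose in stroma. Lipf, a lipase of lingual glands (chromosome 19, 33961187 to 33976810), rose by 7.45 ± 1.06 (7.53 ± 5.78 against 0.17 ± 0.34, n = 3 and 4, adjusted p = 1.03e-05). With it rose the mucin Muc5b (5.88 ± 0.93, 6.43e-05), the secreted proteins Bpifb1 (6.93 ± 1.14, adjusted p = 0.000135), Dmbt1 (4.65 ± 0.81, 0.000526) and Bpifa2 (5.77 ± 1.06, 0.00127) and the trefoil factor Tff2 (4.54, adjusted p = 0.0021). S100a9 (4.94 ± 0.91, adjusted p = 0.00136) and S100a8 (4.79 ± 0.90, 0.00181), the calprotectin subunits of stressed keratinocytes and neutrophils, rose too, as did the defensin Defb14 (4.12, 0.00259) and the muscle gene Actn3 (3.62, 0.00295). Gland genes were unevenly spread: the salivary gland score was 4.70 and 4.63 in tumor stroma 1 and 2, 1.10 in tumor stroma 3 and 4.40 in tumor epithelium 1. The SEs and p-values of such genes rest mostly on a spread pooled over genes (prior degrees of freedom 71.8 against 8 residual). They understate the spread of Lipf itself, whose SD was 5.78 in tumor stroma. In all, 21 genes rose and 0 fell of 14883, with 416 at an unadjusted p under 0.05. With library weights by default and gene by gene, 19 of 189 and 80 of 358 called genes were lower. The smallest p in the negative direction belonged to Arhgap8 (-2.87), Batf3 (-2.36) and P2rx1 (-2.22).

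For tumor against dysplasia stroma, the stress keratin and wound response list rose (6 of 7 positive, median 3.86, 3 past the test, 6 adjusted over the list alone, limma fry adjusted p = 0.0207). It held with an estimated correlation (adjusted p = 0.0044). Krt16 rose by 4.21 ± 0.96 and Aqp5, a water channel of gland cells, by 2.88 (adjusted p = 0.0299 each), and Il1f6, an interleukin of the epithelium, by 3.87 (0.00696). The salivary gland list had 5 of 5 positive (median 2.88, 3 past the test, 4 adjusted over the list alone) and an adjusted p of 0.0844 with fry, 0.0046 with camera and 0.000135 without tumor stroma 3. The stress list was lost in 8 of 22 alternatives, among them without dysplasia stroma 1 (0.0590), 2 (0.0612), 3 (0.0553) or 4 (0.0763), and with age (0.0762), the muscle score (0.0714) as a covariate or a pseudocount of 0.1 (0.0688). The muscle score was 4.55 ± 1.36 in dysplasia and 6.36 ± 0.74 in tumor stroma. Without tumor stroma 2 only 1 gene passed, Lipf, while without tumor stroma 1 12 did, without dysplasia stroma 3 9, and 0 after median centring, after rescaling or with a pseudocount of 0.1. Krt16 held in 6 of 21 alternatives and was lost without dysplasia stroma 2 (0.194) or 4 (0.114) or tumor stroma 1 (0.0797) or 2 (0.874). Aqp5 held in 7 of 20 and was lost without dysplasia stroma 1 (0.0745), 2 (0.0780) or 3 (0.366) or tumor stroma 1 (0.147) or 2 (0.874).

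Against normal stroma, tumor stroma had S100a8 (chromosome 3, 90668978 to 90670035) higher by 7.30 ± 0.98 (7.32 ± 0.90 against 0.17 ± 0.29, n = 3 and 3, adjusted p = 1.66e-06) and S100a9 (chromosome 3, 90692632 to 90695721) by 6.63 ± 1.00 (7.63 ± 1.39 against 0.91 ± 0.80, adjusted p = 2.41e-05). The cytokine Il1b rose by 4.52 ± 1.01 (5.48 ± 1.35 against 0.81 ± 0.53, adjusted p = 0.0322). The gland genes Lipf (7.25 ± 1.16, 9.19e-05), Bpifb1 (7.10, 0.000517), Muc5b (5.79, 0.000517), Dmbt1 (4.97, 0.000687), Bpifa2 (5.52, 0.0137), Tff2 (4.32, 0.0285) and Bpifb2 (4.27, 0.0322) rose as well. The same 2 tumor libraries held the high values of these genes, whose p-values rest mostly on a spread pooled over genes. In all, 12 genes rose and 0 fell, with 277 at an unadjusted p under 0.05. There were 28 up and 11 down under default library weights and 212 up and 138 down under gene-by-gene weights. In the negative direction the smallest p belonged, among the genes reported, to Lyg1 (-3.98) and the hard keratin Krt32 (-2.99). S100a8 passed in each of 20 alternatives, with a highest adjusted p of 0.0361, but not with the salivary gland score as a covariate (7.05 ± 1.56, adjusted p = 0.0871). Without tumor stroma 2 the count was 2 and Lipf had 4.98 (adjusted p = 0.261), and without tumor stroma 1 it was 7. Il1b was lost without any normal library (0.0821, 0.0912 and 0.0928 for normal stroma 1, 2 and 3), tumor stroma 2 (0.905) or tumor stroma 3 (0.0751).

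Stress keratin and wound response was the only list to pass in tumor against normal stroma (7 of 7 positive, median 3.55, 2 past the test, 5 adjusted over the list alone, limma fry adjusted p = 0.0121, and 0.0011 with an estimated correlation). It was lost without normal stroma 3 (0.0504) and with age as a covariate (0.158). The neutrophil score was 2.21 ± 0.22 in tumor, 1.23 ± 0.40 in normal and 1.31 ± 0.46 in dysplasia stroma, and its list did not pass against normal (median 0.69, limma fry adjusted p = 0.706) or dysplasia (0.74, adjusted p = 0.722). The salivary gland list (5 of 5 positive, median 2.76, 2 past the test, 4 adjusted over the list alone) had an adjusted p of 0.158 with fry, 0.0059 with camera and 0.000341 without tumor stroma 3. Filiform papilla genes had a median of -1.97 (adjusted p = 0.158, and 0.0384 with camera, 0.0273 without normal stroma 1 and 0.0314 without tumor stroma 2). Inflammatory cytokines had 0.96 with 16 of 17 positive (1 past the test, 4 adjusted over the list alone, adjusted p = 0.280, and 0.0384 with camera). Of the genes called up against dysplasia and against normal stroma, 11 were shared, among them S100a8, S100a9, Lipf, Muc5b and Spp1. These comparisons share the 3 tumor libraries. Unchanged groups simulated that way shared 32.8 genes on average, all of them in 1 of 100 draws with 3279, while independent lists would share 0.0169.

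**Figure D4:**
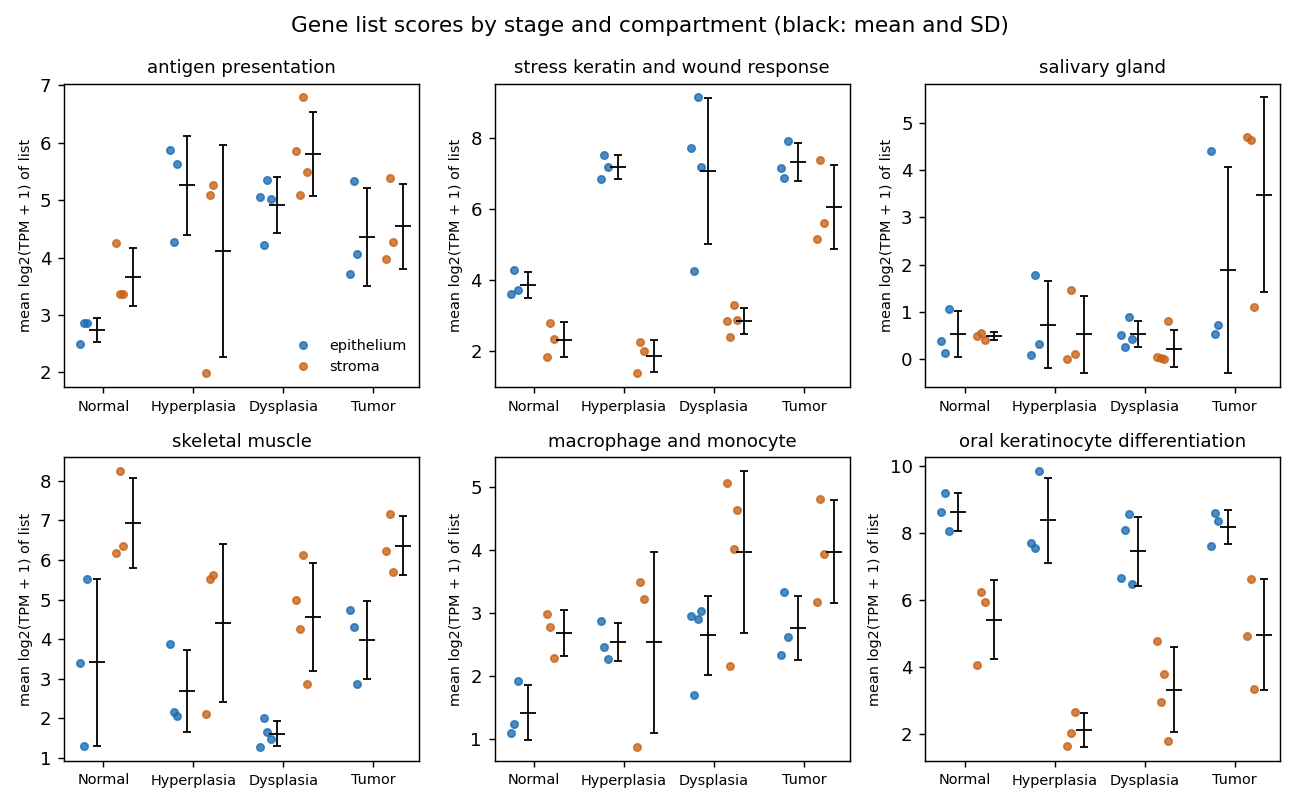
Each panel gives the mean log2(TPM + 1) of a gene list per library by stage, with epithelium in blue, stroma in orange and the mean and SD in black. The salivary gland score is 4.70 and 4.63 in 2 tumor stroma libraries and 4.40 in 1 tumor epithelium library, and the muscle score is 3.97 in tumor and 1.61 in dysplasia epithelium.

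Among the 4 stages of epithelium, limma's F test called 23 genes, led by B2m, Spink6 (3.75, 1.49, 0.07 and 0.67 from normal to tumor) and Gprc5d, with 713 at an unadjusted p under 0.05. Krt17, another stress keratin, was among them (6.30, 9.23, 10.22 and 9.98) and was chosen after it was seen. The count was 0 and 10 without normal epithelium 1 and 2, 39 and 67 without hyperplasia epithelium 2 and 3, 9, 221 and 13 without dysplasia epithelium 1, 2 and 4, and 36, 14 and 12 without tumor epithelium 1, 2 and 3. In stroma the F test called 29 genes, led by S100a8, Lipf and S100a9, with 715 at an unadjusted p under 0.05. That count was 64 without normal stroma 1, 3, 15 and 113 without hyperplasia stroma 1, 2 and 3, 62, 16 and 51 without dysplasia stroma 1, 3 and 4, and 19, 16 and 59 without tumor stroma 1, 2 and 3.

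Whether the change from normal to tumor differed between compartments was tested within the pairs. Smallest in p in the positive direction, epithelium minus stroma, were Fmc1 (3.09), the folate receptor Folr2 (2.95) and Pxmp2 (2.72). In the negative direction they were Spink6 (-3.31), Exoc3l4 (-3.09) and the embryonic myosin Myh3 (-2.02). The sign does not tell in which compartment the change was larger, since Spink6 fell in tumor epithelium. With limma 0 genes passed of 15499, with 236 at an unadjusted p under 0.05 and 0 with library weights, and of 37 lists 0 passed, with a smallest adjusted p of 0.757. B2m had a difference of 2.65 ± 0.95 and Lipf of -4.76 ± 1.44, neither of which passed. The genes called in a single compartment are therefore not shown to differ between compartments.

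For the genes of the immunostained markers, no step passed in either compartment. In epithelium Ptprc was at 2.66 ± 0.76 in normal tissue, 3.94 ± 0.46 in hyperplasia, 4.12 ± 0.28 in dysplasia and 3.77 ± 0.31 in tumor, a difference of 1.26 ± 0.46 for hyperplasia (adjusted p = 0.917). In stroma it was at 3.83 ± 0.25, 5.18 ± 0.78, 5.49 ± 1.34 and 5.31 ± 0.89. Cd163, the M2 marker, was at 2.79 ± 0.55, 1.77 ± 1.59, 3.70 ± 0.93 and 2.2 ± 0.62 in stroma, and Cd4 at 1.49 ± 0.70, 1.81 ± 1.65, 1.64 ± 1.82 and 3.02 ± 0.22. Foxp3 means in stroma were between 0.32 and 1.43, against an olfactory receptor background of 0.40 to 2.36 per stroma library. Nos2, the gene of iNOS, reached a TPM of 1 in fewer than 3 stroma libraries and was not tested there, with 5.89 in dysplasia stroma 3.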

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

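Of the tests in this part, the number of equally large splits of the samples and the gland covariate were planned before the data were examined, and the others were chosen after the results were seen. In groups of 4 libraries, the highest or lowest library was set against the other 3 by Dixon's test. Of 128 genes, list scores and library measures tested that way, 14 had a library standing apart. Chance would give about 6.4 among independent tests. These were all read in the dysplasia epithelium or dysplasia stroma libraries and are not independent, so an excess over chance cannot be judged.

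All 14 lay in dysplasia groups, since the other groups hold 3. Dysplasia epithelium 2 had a macrophage score of 1.70 (2.90 to 3.02 in the others) and 18.2% of its TPM in Lars2, March6 and D17H6S53E (0.24 to 0.68 in the others). Dysplasia stroma 2 had 55.0% there (0.40 to 9.41 in the others), and it was low in S100a9 (0.80 against 3.02 to 3.43), the matrix score (4.17 against 5.57 to 5.81), the type I interferon score (1.89 against 3.22 to 3.38) and the immunostained marker score (1.77 against 2.89 to 2.96). Its adipocyte score was high (1.92 against 1.70 to 1.72). Dysplasia stroma 3 was high in the score of genes often altered in oral carcinoma (5.56 against 3.70 to 3.90) and in ribosomal protein genes (9.02 against 6.58 to 6.94). In dysplasia stroma 4, Lipf was at 0.69, Defb14 at 1.53 and Aqp5 at 1.78, all listed at 0 in the others, where any value stands apart by this test. These levels lie near the olfactory receptor background of that library (mean 1.46). Its salivary gland score was 0.81 (0 to 0.05 in the others).

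Rows of genes that stand several times in the table were not used in the comparisons, and 7 of them were higher than in normal tissue past limma's threshold. In hyperplasia epithelium these were a row of Chil4, a chitinase-like gene (9.11, adjusted p = 0.0105), Krt6a, a stress keratin (3.19, 0.0219), Cyp2b10 (2.21, 0.0235), the interferon-induced Oas1c (3.02, 0.0210) and 2 rows of the MHC class I gene H2-Bl (3.00, 0.0380, and 3.97, 0.0126). In tumor stroma it was a row of the amylase gene Amy2 (5.54, 0.0227). Lower in hyperplasia epithelium were 3 rows of the keratin-associated gene Krtap4-2 (-4.32, -4.59 and -4.45, adjusted p = 0.0126, 0.0210 and 0.0126) and a row of Krtap9-3 (-3.42, 0.0107). Against dysplasia stroma, rows of Amy2 (4.58, 0.0484), Chil4 (3.60, 0.0159) and Gm45826 (2.56, 0.0484) were higher in tumor stroma. Each of these genes has close copies, so its value is uncertain.

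Hyperplasia stroma had a median log2 change over genes of -0.72 against normal stroma. Whether the share that Lars2, March6 and D17H6S53E take of the total was the cause could not be decided. The median was -0.55 with TPM rescaled without them, but rescaling leaves genes listed at 0 where they are. Without hyperplasia stroma 1, which had 87.0% of its TPM in Lars2, March6 and D17H6S53E and 9382 genes listed at 0, the median was 0.16. This library may therefore account for the lower median, which the other 2 hyperplasia libraries together did not show.

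Stress keratin and wound response genes rose in tumor stroma (median 3.55). Gland tissue in the dissected regions stayed open: with the salivary gland score as a covariate, the median was 2.24 (fry adjusted p = 0.555), Lipf stood at -0.36 ± 1.43 against 7.25 ± 1.16 without it, and S100a8 stood at 7.05 ± 1.56 (adjusted p = 0.0871) against 7.30 ± 0.98. A larger share of epithelium also stayed open, since the differentiation score changed by -0.32 with a 95% interval of -2.87 to 2.24, against 3.72 (2.35 to 5.10) for the stress score. A basal keratinocyte score was tried first (0.22, -2.27 to 2.70) and set aside because that list did not separate the compartments (median 0.94, adjusted p = 0.113). An unchanged share of epithelium with higher stress genes of its own could not be excluded either. The list's median in tumor epithelium was 2.66, with a range of 0.32 to 6.22 from resampling the genes. Unlike the intervals above, that range does not measure the spread between libraries. A change in the stroma of tumors, or its neutrophils (score 2.21 against 1.23 in normal stroma), remains possible and untested.

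In hyperplasia epithelium, 7 MHC class I pathway genes had a median change of 2.83. Scaling between libraries was argued against, since the median was 2.71 and 2.84 under the 2 other scalings. More leukocytes in the dissected epithelium stayed open: 19 leukocyte genes with a mean log2 value of at least 2 had a median of 1.30 (0.01 to 1.77), with 14 positive. That range came from resampling the genes, so it does not measure the spread between libraries. Among the leukocyte genes, Ctss was at 2.48 and Cd3d at -0.12. A rise within keratinocytes may be a further explanation, and it was not tested.

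Other splits of the samples were too few for a share under 0.05 in 5 comparisons. There the real count and the highest of the other splits were 5 and 5 for hyperplasia against normal epithelium (2 of 10 splits as large), 7 and 0 for tumor against normal epithelium (1 of 10), 1 and 0 for hyperplasia against normal stroma (1 of 10), 12 and 8 for tumor against normal stroma (1 of 10), and 0 and 0 for the difference between compartments (10 of 10, as any split gives at least 0). Chance was not excluded for the 21 genes of tumor against dysplasia stroma (2 of 35 splits as large, highest other 24) or for the 23 genes of the F test in epithelium (7 of 100, highest other 3012). The comparison decides nothing for counts of 0, which every split reaches, in dysplasia against hyperplasia epithelium (35 of 35, highest other 64), tumor against dysplasia epithelium (35 of 35, highest other 5) and dysplasia against hyperplasia stroma (35 of 35, highest other 8). Chance was argued against for the 4677 genes between compartments (1 of 100, highest other 416). For the 29 genes of the F test in stroma, 2 of 100 splits were as large, the real one included, a share under 0.05. Chance was not excluded there, since another split gave 2398 genes and libraries may share an animal. The splits with 3012, 2398 and 64 genes point to a structure among the samples besides stage, and what produced them was not tested.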

How the results depend on the processing

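Gene-by-gene library weights, all rows, median centring, rescaling without Lars2, March6 and D17H6S53E, and leaving out hyperplasia stroma 1 and dysplasia stroma 2 together were chosen after the data were seen, and the other alternatives before. Between compartments the count of 4677 lay between 3527 (pseudocount 0.1) and 5939 (default library weights), with 3706 without pairing, 4228 rescaled and 3481 to 5374 without 1 pair. For the difference of the tumor change between compartments every alternative that was run gave 0. Counts below are in the order hyperplasia against normal, dysplasia against hyperplasia, tumor against dysplasia, tumor against normal and F test, which gave 5, 0, 0, 7 and 23 in epithelium and 1, 0, 21, 12 and 29 in stroma. Except where noted, the cause of a move was not tested.

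Epithelium had 2, 0, 0, 4 and 3 genes with a pseudocount of 0.1; 3, 0, 0, 4 and 8 without a filter; 17, 0, 0, 13 and 33 with the stricter filter; and 6, 0, 0, 11 and 20 without run. Quantile normalization gave 23, 0, 0, 59 and 54, median centring 4, 0, 0, 12 and 1, rescaling 13, 0, 0, 28 and 28, and all rows 18, 0, 0, 0 and 34. Age as a covariate gave 10, 0, 0, 3 and 20. Default library weights gave 1786, 2963, 1857, 604 and 4339, and gene-by-gene weights 464, 256, 1423, 582 and 1963. Leaving out 1 library gave 0 to 30, 0 to 5, 0 to 8, 0 to 25 and 0 to 221.

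Stroma had 0, 0, 0, 1 and 0 genes with a pseudocount of 0.1; 0, 0, 18, 6 and 21 without a filter; 1, 0, 4, 4 and 16 with the stricter filter; and 1, 0, 14, 5 and 18 without run. Quantile normalization gave 0, 0, 3, 7 and 4, median centring 0, 0, 0, 2 and 0, rescaling 0, 0, 0, 2 and 0, and all rows 1, 0, 21, 11 and 37. Age as a covariate gave 108, 2, 18, 7 and 106, and the muscle score 0, 0, 3, 15 and 16. Default library weights gave 473, 1663, 189, 39 and 1821, and gene-by-gene weights 3, 0, 358, 350 and 699. Without hyperplasia stroma 1 and dysplasia stroma 2 the counts were 0, 0, 6, 11 and 13, with fewer samples. Leaving out 1 library gave 0 to 94, 0 to 38, 1 to 26, 2 to 15 and 3 to 113.

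The replicate number of the titles as a block gave 5, 0, 0, 5 and 3 genes in epithelium and 9, 1, 18, 13 and 36 in stroma, and the stress list in tumor against dysplasia stroma had an adjusted p of 0.0895. Libraries of the same number in different stages had deviations that correlated between -0.73 and 0.58, and 10 of 36 pairs were over 0.1. Only 3 libraries were closest to their own number. Whether libraries of the same number share an animal cannot be told from these values.

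Of the values for single genes that did not pass in the analysis reported, 8 passed in the opposite direction under an alternative, while 905 under other settings and 638 with 1 library left out changed sign without passing. With default library weights, which did not converge, the 8 included Krt36 (2.40) in dysplasia against hyperplasia epithelium, Aldh3a1 (1.48) in tumor against dysplasia epithelium, Cd8a (1.67) in hyperplasia against normal stroma, and Acta1 (-2.70), Lpl (-1.37) and Cd8a (-1.34) in dysplasia against hyperplasia stroma. With gene-by-gene weights they were Aldh3a1 (1.45) in tumor against dysplasia epithelium and Igkc (-4.30) in tumor against dysplasia stroma. The cause was not tested.

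For genes called, 1641 values under other settings stayed past the threshold and 248 did not, and 1612 and 157 with 1 library left out. For lists called these were 253 and 37, and 247 and 26. Both totals come mostly from epithelium minus stroma, which had 9 lists up and 11 down and where most named genes held in 25 of 25 alternatives. Calls between stages were lost more often. Of the named genes called there, only S100a8 in tumor against normal stroma held in all alternatives, and Krt16 in tumor against dysplasia stroma held in 6 of 21. Values not called passed 225 times for genes and 73 for lists under other settings, and 27 and 10 times with 1 library left out. The 22 list calls of all comparisons became 53 with quantile normalization, 38 with median centring and 6 with camera, and 18 to 28 under the other 5 settings run for all comparisons. The stress list in tumor stroma held in 14 of 22 alternatives against dysplasia (adjusted p from 0.000765 to 0.0895) and 19 of 21 against normal (0.000621 to 0.158). B2m in hyperplasia epithelium held in 16 of 18, and S100a8 in tumor against normal stroma in 20 of 20, a count that leaves out the fit with the gland score (adjusted p = 0.0871). Weakly held against normal were Krt76 in hyperplasia stroma (9 of 20), Pthlh in tumor epithelium (6 of 18) and Bpifb2 (6 of 19), Tff2 (7 of 19), Il1b (8 of 20) and Bpifa2 (9 of 20) in tumor stroma. No depth is stated for these libraries, so what depth limits could not be given beyond the background of olfactory receptor genes.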

Other observations

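The genes given here were chosen from the F tests among stages after their values were seen, and no test of them as a group was run. In epithelium, Krtap4-16, a keratin-associated protein, was at 6.23 ± 0.87 in normal tissue and at 1.49 ± 2.28, 0.47 ± 0.91 and 2.74 ± 1.86 in hyperplasia, dysplasia and tumor (limma adjusted p = 0.0128, n = 3, 3, 4 and 3). Lrrc15 (6.10, 1.95, 1.08 and 3.25, adjusted p = 0.0381), Dsg4, a desmosomal cadherin (3.53, 1.11, 0.80 and 1.40, adjusted p = 0.0387), Wfdc2 (4.30, 1.57, 1.21 and 2.22, adjusted p = 0.0381) and the heparan sulfate enzyme Hs3st5 (3.05, 1.59, 0.56 and 1.45, adjusted p = 0.0128) followed the same order of normal above the others. The homeobox gene Irx2 was lowest in normal epithelium (0.64, 3.49, 4.10 and 2.31, adjusted p = 0.0128), as was the complement gene C1qc (0.84, 1.92, 3.18 and 2.89, adjusted p = 0.0412).

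In stroma, the hair keratin Krt36 (5.39 ± 2.06 in normal tissue, then 0.86, 0.91 and 1.68, limma adjusted p = 0.00541), Krtap3-1 (4.46, 0.49, 0.77 and 2.39, adjusted p = 0.0381) and Lyg1, a lysozyme-like gene (5.70, 1.18, 0.98 and 1.66, adjusted p = 0.00712), had the same order. The muscle genes Mybph (3.98, 1.31, 0.64 and 3.78, adjusted p = 0.0458) and Jsrp1 (4.35, 1.78, 0.41 and 3.42, adjusted p = 0.0294) were lowest in dysplasia. The keratinocyte genes Gjb2 (2.92, 0.35, 2.35 and 5.99, adjusted p = 0.00223) and Krt17 (4.52, 3.08, 4.97 and 8.81, adjusted p = 0.00256) were highest in tumor stroma.

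No lymphoid list passed limma fry between the compartments, though 1 of 17 T cell genes, Cd2 (-0.79 ± 0.28, limma adjusted p = 0.0345), and 1 of 14 B cell and plasma cell genes, Igkc (-1.39 ± 0.50, adjusted p = 0.0369), were lower in epithelium. Each held in 15 of 25 alternatives. Epithelium minus stroma had a median of -0.25 for T cell genes (limma fry adjusted p = 0.336), -0.03 for cytotoxic and NK cell genes (0.428), -0.08 for regulatory T cell and checkpoint genes (0.544) and -0.37 for B cell and plasma cell genes (0.117). Neutrophil (-0.09, 0.550), M1 macrophage (-0.06, 0.550) and taste bud genes (-0.26, 0.450) did not pass either, with 0 of 8, 1 of 15 and 1 of 8 members past the test. The iNOS gene Nos2 stood at 5.89 in dysplasia stroma 3 and at no more than 1.5 in the other 25 libraries.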
